A study of Mus musculus with 47 samples.

How the data were processed

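The samples were 47 mouse liver libraries from C57BL/6J, CAST/EiJ and NZO/HlLtJ mice of both sexes on a 10% fat control diet (23 libraries) or a 44% fat diet (24 libraries). Per the labels, polyadenylated RNA libraries were made with a KAPA mRNA HyperPrep kit, with ERCC spike-in RNA added, and sequenced as paired-end reads on a NovaSeq 6000. The authors deposited expected counts per gene (estimated counts that need not be whole) and a second table of variance-stabilized values on a log2 scale. Reads were not used here. The values show the first unit: 20.3% of deposited values were not whole (tolerance 1e-06), and totals differ between libraries. Per the submitters' processing notes, the genome build was GRCm38 and DESeq2 was used, with no versions given. The aligner, the counting tool, its use of strand and the annotation release are not given in the sources used here. The deposited annotation gave gene symbols and GRCm38 coordinates. Every gene in the table had a count above 0 in at least 24 libraries, so genes below that are not analysed here. Spike-in reads were not used here.

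Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr over the 12 groups of strain, sex and diet, which kept 16650 of 20320 genes, and libraries were scaled with TMM factors. One quasi-likelihood model (estimateDisp, then glmQLFit with robust estimation) was fitted to all 47 libraries with 12 group means, giving 35 residual degrees of freedom, so that all comparisons share an estimate of spread. Diet effects within a strain were averaged over the sexes, strain effects over sexes and diets, and sex effects over diets. Interactions were differences of diet effects, and a joint test asked whether the diet effect differed among the 3 strains. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a single gene is from this edgeR test unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of its F statistic. Group values are CPM scaled by the TMM factors, as mean ± SD.

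Before the data were examined, 34 gene lists were fixed, covering lipid, glucose, amino acid and drug metabolism, stress, inflammation, clock, sex-biased genes and markers of the liver's cell types and of possible foreign cell types. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. List p-values are Benjamini-Hochberg adjusted over the 34 lists of a comparison. By diet the preset correlation called 12, 8 and 19 lists in C57BL/6J, CAST/EiJ and NZO/HlLtJ, the estimated one 0, 0 and 0, and fry 0, 2 and 9. For each list the members called over all genes and those called when adjusted over the list alone were counted.

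The naming rule was also fixed before the data were examined. Genes with a symbol other than Gm or Rik names and an average of at least 1 log2 CPM were eligible. For diet the 10 highest and 10 lowest log2 fold changes among called genes with the same sign in both sexes were named, for the joint test the 12 smallest p-values, for sex-by-diet the 6 smallest p-values among called genes, and for strain and sex the 5 highest and 5 lowest among called genes of at least 3 log2 CPM. To these were added up to 4 list members with the smallest p and 17 genes named in advance, from Cidea to Col1a1, with Xist, Uty and Kdm5d as a check of sex. The symbols of 39 genes are duplicated, and 4887 genes have Gm or Rik names.

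Changes were planted in counts of 16259 genes simulated at means, library sizes and spread from the data. For diet in C57BL/6J, CAST/EiJ and NZO/HlLtJ, 74.6%, 71.6% and 77.6% of 1.5-fold and 97%, 95.5% and 95.5% of 2-fold changes were recovered. Of calls 3.7%, 7.8% and 3.8% were false. Recovery at low expression was not counted apart, and real tests may do worse. The closest pair of any group differed by a chi-square per gene of 32.1 or more, so no library was counted as a duplicate. The labels do not state that each library is a separate animal, so p-values measure the spread between these samples.

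Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no expression filter, a stricter filter (1 CPM in at least 4 libraries), a fold of at least 1.5, each strain fitted alone, each library left out, the run of consecutive sample identifiers as a covariate or taken singly, and limma on the deposited variance-stabilized values. The sample titles fall into 3 runs of consecutive identifiers with 16, 16 and 15 libraries, treated as possible batches. Added after seeing the data were a fit without the 5 libraries with Cpa1 of at least 20 CPM, a fit with a clock score per library as covariate (mean standardized Dbp and Ciart minus Arntl and Npas2), and leaving out each library for the list counts. Named genes were refitted under 7 of these settings and with each library left out. Whether groupings at random give as many calls was counted over 100 splits of the libraries within strata, 50 for strain and 35 within a single sex of a strain. Ddx3y and Eif2s3y are not analysed here. Some genes under the naming rule are not reported here.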

Results

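Liver RNA was measured in 47 libraries from mice of 3 inbred strains, both sexes and 2 diets. C57BL/6J is the common laboratory strain, CAST/EiJ is a wild-derived strain, and NZO/HlLtJ is the New Zealand Obese strain, which carries many obesity and diabetes alleles. Mice ate a control diet with 10% fat or a high-fat, high-sugar diet with 44% fat, both with added fiber, from week 6, and tissue was taken at week 15. The series asks how genotype and diet interact in mouse models of type 2 diabetes. Each of the 12 groups held 4 libraries, except CAST/EiJ males on 10% fat with 3. Total counts ran from 21.6 M to 47.8 M counts per library, with means of 40.8 M in C57BL/6J, 37.7 M in CAST/EiJ and 39.9 M in NZO/HlLtJ. In NZO/HlLtJ males on 44% fat the totals ran from 21.6 to 40 M, against 36.6 to 45.7 M in NZO/HlLtJ males on 10% fat. Of 20320 genes in the count table, 16650 passed the expression filter and were tested.

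Sex-linked genes matched the sex given in the labels in all 47 libraries. Xist, the X-inactivation transcript, lay between 794.8 and 1353.3 counts per M (CPM) in the 24 female libraries and between 0 and 4.3 CPM in the 23 male libraries. The Y-linked genes Uty (9.5 to 23.3 CPM) and Kdm5d (14.2 to 23 CPM) were present in every male library, in females at most 0.03 and 0.1 CPM. Within groups, replicate correlations ran from 0.962 to 0.988. Pancreatic acinar transcripts stood at 20 CPM of Cpa1 or more in 5 libraries, the acinar libraries, with Cpa1 (carboxypeptidase A1) at 81 and 41 CPM in C57BL/6J female 44% fat replicates 1 and 2, 41.4 and 74.2 CPM in C57BL/6J male 10% fat replicates 2 and 3, and 47.1 CPM in CAST/EiJ female 44% fat replicate 2. Other libraries had lower levels, at most 12.2 CPM in C57BL/6J female 44% fat replicate 4 and then 9.2 CPM in CAST/EiJ male 10% fat replicate 2.

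In C57BL/6J, 3 of 18 lipid droplet genes rose on the 44% fat diet, a list with adjusted p = 0.718 with an estimated correlation, and the leptin receptor gene fell. Cidec, a lipid droplet protein, rose from 1.267 ± 1.5 to 6.347 ± 6.19 CPM (SD, n = 8 per diet; log2 fold change 2.56, SE 0.55, adjusted p = 0.0139). Mmd2 (ENSMUSG00000039533, chromosome 5: 142562358 to 142608800, GRCm38) rose from 2.298 ± 1.22 to 8.259 ± 7 CPM (log2 fold change 1.77, SE 0.24, adjusted p = 3.99e-05). Lepr, which encodes the leptin receptor (chromosome 4: 101717404 to 101815352), fell from 61.92 ± 43.2 to 23.5 ± 17 CPM (log2 fold change −1.45, SE 0.29, adjusted p = 0.00768). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 165 genes changed, 137 higher and 28 lower on 44% fat, of which 66 changed by at least 1.5-fold.

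Pls1, an actin-bundling protein of microvilli (log2 fold change 1.84, SE 0.29, adjusted p = 4.90e-04), and Slc10a2, the ileal-type bile acid transporter (1.49, SE 0.26, adjusted p = 0.00225), rose. So did the cell-surface proteoglycan Gpc1 (1.07, SE 0.22, adjusted p = 0.012) and the thioesterase gene Them7 (0.81, SE 0.10, adjusted p = 1.68e-05). These 4 passed in all 23 refits made with the other strains in the model. Smpd3, a sphingomyelinase, rose by a log2 fold change of 1.87 (adjusted p = 0.0197), up to 0.164 without C57BL/6J male 44% fat replicates 2 or 4, male 10% fat replicate 3, or the acinar libraries. The prostaglandin transporter Slco2a1 (−0.58, adjusted p = 0.004) and Abca2 (−0.47, adjusted p = 8.53e-04) fell, and lost the threshold without the acinar libraries (adjusted p = 0.0643 and 0.0578), as did Lepr (0.0776). Spaca6 fell (−0.85, adjusted p = 0.0147; 0.0521 without C57BL/6J male 44% fat replicate 2). Tpm2, Adora1, Ighm, Robo1, Wnk4, Adamdec1, Mpzl1, Cyp39a1, Leng9 and Abhd8 also passed, each losing the threshold in 5 to 15 of the 23 refits.

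Of 18 tested lipid droplet genes in C57BL/6J, 3 rose, the same number when adjusted over the list alone: Cidec, Fitm1, an endoplasmic reticulum protein of droplet formation (1.03, SE 0.18, adjusted p = 0.00225), and the acyltransferase Mogat1 (1.67, SE 0.42, adjusted p = 0.0394). Cidec reached adjusted p = 0.0869 at most, without the acinar libraries or C57BL/6J female 44% fat replicate 1, and Mogat1 lost the threshold in 15 of 23 refits. The list was higher by camera (adjusted p = 0.00389, or 0.718 with an estimated correlation). The uncalled adipocyte list averaged 0.621. Respiratory chain genes had a median log2 fold change of 0.13, with 0 of 17 called over all genes and 9 higher adjusted over the list alone (camera adjusted p = 6.35e-08; adjusted p = 0.718 with an estimated correlation). Fatty acid oxidation (median 0.12, 0 of 34 called, 6 higher adjusted over the list alone) and glycolysis and fructose metabolism (median 0.23, 1 of 16 called, 2 higher adjusted over the list alone) each had camera adjusted p = 7.55e-05 and adjusted p = 0.718 with an estimated correlation.

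The amino acid catabolism genes Bckdhb (0.32, SE 0.06, adjusted p = 0.00678) and Gpt2 (0.51, SE 0.11, adjusted p = 0.012) rose in C57BL/6J, with adjusted p = 0.0841 and 0.104 without the acinar libraries. Their list of urea cycle and amino acid genes had 2 of 21 members called and 4 adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.718 with an estimated correlation). Collagen and stellate cell genes had a median of 0.38, with 0 of 21 called and 1 adjusted over the list alone, and cell cycle genes a median of 0.60, with 0 of 20 called and 1 adjusted over the list alone. Both had camera adjusted p = 3.25e-04 and adjusted p = 0.718 with an estimated correlation. In C57BL/6J female 44% fat replicate 1 these lists stood 1.66 and 2.21 log2 units above the group median, and glutathione genes 1.36 above, while female-biased genes stood 2.4 below. Interferon response genes (median 0.27, 0 of 22 called, camera adjusted p = 8.04e-05), mitochondrially encoded genes (0.19, 0 of 13, 7.55e-05), glutathione genes (0.13, 0 of 16, 0.0075) and fatty acid synthesis genes (0.29, 0 of 20, 0.0318) stood higher, and female-biased liver genes lower (−0.44, 0 of 18, 0.0358). Adjusted over the list alone, 1 mitochondrially encoded and 5 glutathione genes were higher and 1 female-biased gene lower. With an estimated correlation these 5 lists had adjusted p of 0.718 to 0.743. Cholesterol synthesis genes did not stand apart (median 0.07, 0 of 24 called, camera adjusted p = 0.716), nor did the remaining fixed lists.

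The C57BL/6J count moved widely with the model and the libraries: DESeq2 called 320 genes, a fit to this strain alone called 4, the fit without the acinar libraries 61, and the fit with a clock score 87. Fits within the 3 runs of consecutive sample identifiers called 3, 70 and 0 genes (edgeR; 747, 1357 and 752 at an unadjusted p under 0.05). Leaving out male 44% fat replicate 3 gave 369 genes, while leaving out female 10% fat replicate 1 gave 85, male 44% fat replicates 1, 2 and 4 gave 109, 67 and 56, and male 10% fat replicate 3 gave 76.

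In CAST/EiJ, 8 of 24 cholesterol synthesis genes fell and 8 of 34 fatty acid oxidation genes rose on the 44% fat diet. Both lists had adjusted p = 0.22 with an estimated correlation. Sqle, the squalene epoxidase of sterol synthesis (ENSMUSG00000022351, chromosome 15: 59315077 to 59331192), fell from 30.1 ± 28.1 CPM (SD, n = 7) to 8.758 ± 10.9 CPM (n = 8; log2 fold change −2.13, SE 0.42, adjusted p = 0.0116). Cpt2, which acts in mitochondrial fatty acid import, rose from 105.2 ± 16.1 to 142.6 ± 16.9 CPM (0.46, SE 0.08, adjusted p = 0.00228). Hamp, the hepcidin gene, fell most, from 11.39 ± 13.4 to 0.1566 ± 0.393 CPM (−6.68, SE 1.09, adjusted p = 7.93e-04). On 10% fat, female replicates 2 and 3 and male replicate 2 had 0 to 0.196 CPM and the others 6.899 to 35. Reads may be shared with Hamp2. By edgeR's quasi-likelihood test 149 genes changed, 83 higher and 66 lower, of which 68 changed by at least 1.5-fold.

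Among 24 cholesterol synthesis genes in CAST/EiJ, 8 fell and 0 rose, and 21 fell when adjusted over the list alone. Their median was −0.82 (camera adjusted p = 2.43e-21; adjusted p = 0.22 with an estimated correlation; fry adjusted p = 0.0222). Besides Sqle they included Cyp51 (−1.29, SE 0.27, adjusted p = 0.015), Dhcr7 (−1.23, SE 0.27, adjusted p = 0.0203), Msmo1 (−1.49, SE 0.33, adjusted p = 0.0235), Pmvk (−1.38), Nsdhl (−1.22) and Tm7sf2 (−0.69, SE 0.15, adjusted p = 0.0191). Without CAST/EiJ male 10% fat replicate 1 all 7 lost the threshold, Sqle at adjusted p = 0.0538. Without other single libraries Dhcr7 lost it for female 10% fat replicates 1 and 4, Tm7sf2 for female 10% fat replicate 4, and Msmo1 for female 10% fat replicate 4, female 44% fat replicate 2 and male 44% fat replicate 4. Adjusted p reached 0.128 for Dhcr7, 0.0769 for Tm7sf2 and 0.103 for Msmo1. Pmvk and Nsdhl lost it in 7 and 13 of 22 refits.

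Of 34 fatty acid oxidation and ketone body genes in CAST/EiJ, 8 rose and 0 fell, and 20 rose when adjusted over the list alone. The list median was 0.38 (camera adjusted p = 2.70e-24; adjusted p = 0.22 with an estimated correlation; fry adjusted p = 0.0222). Examples beside Cpt2 were Acadl (0.38, SE 0.08, adjusted p = 0.0155) and the carnitine carrier Slc25a20 (0.47, SE 0.10, adjusted p = 0.0156). These 2 lost the threshold without CAST/EiJ male 10% fat replicates 1 or 2 (adjusted p up to 0.0702 and 0.0769). Hsd17b4, a peroxisomal oxidation enzyme, rose from 379.2 ± 26.9 to 508.9 ± 35.2 CPM (0.42, SE 0.07, adjusted p = 4.81e-04). The fatty acid binding protein Fabp2 rose from 72.99 ± 11.2 to 121 ± 10.9 CPM (0.72, SE 0.13, adjusted p = 0.0045). Both, with Cpt2, passed in all 22 refits.

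**Figure D1:**
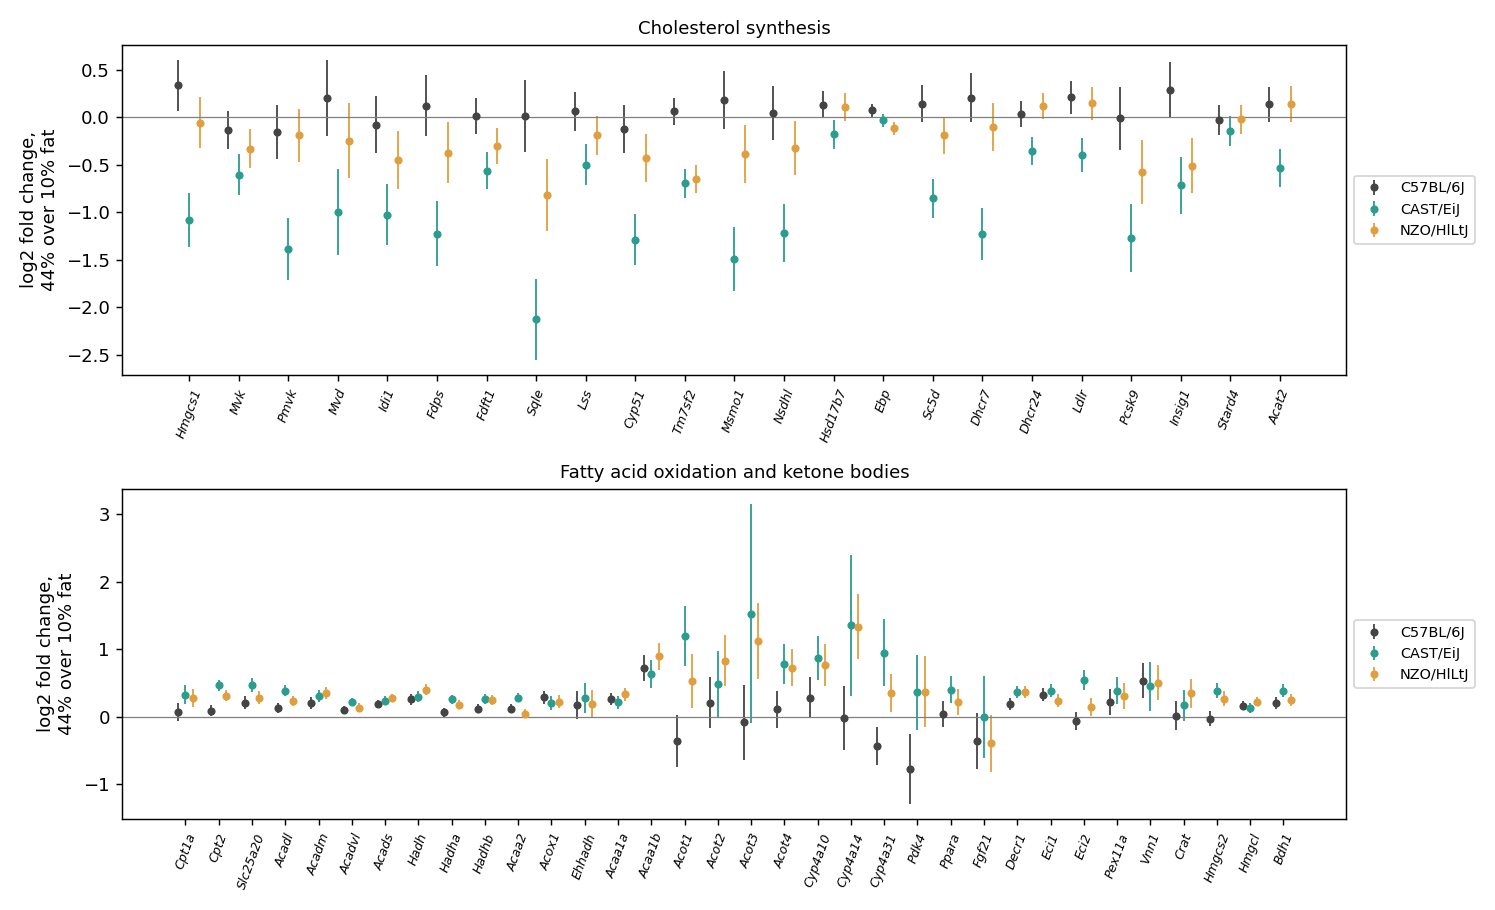
Diet log2 fold change (44% over 10% fat, ± 1 SE) of cholesterol synthesis genes and of fatty acid oxidation and ketone body genes in the 3 strains. In CAST/EiJ the medians of the full lists were −0.82 and 0.38, in NZO/HlLtJ −0.22 and 0.29, and in C57BL/6J 0.07 and 0.12.

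Chrna2, a nicotinic receptor subunit, rose in CAST/EiJ from 10.92 ± 13.8 to 56.78 ± 49.8 CPM (2.06, SE 0.32, adjusted p = 4.81e-04). Vwf, the von Willebrand factor of endothelium, rose (0.79, SE 0.11, adjusted p = 1.26e-04), and Fras1, an extracellular matrix protein, fell (−1.75, SE 0.25, adjusted p = 1.82e-04). All 3 passed in every refit. Rgs4 (1.10, adjusted p = 0.0142) and Cyp4a12b (1.67, adjusted p = 0.0136; shared reads with Cyp4a12a are possible) rose, and the histidine catabolism gene Hal fell (−0.70, adjusted p = 0.0142). These 3 lost the threshold without CAST/EiJ male 10% fat replicate 1 (adjusted p = 0.0769, 0.0527 and 0.0769). Gpc1 rose (1.01, adjusted p = 0.0235, up to 0.0769 without female 10% fat replicate 1 or male 10% fat replicates 1 or 2). Rdh11 fell (−1.12, adjusted p = 0.0238, up to 0.141 without male 10% fat replicate 1, female 10% fat replicate 4 or male 44% fat replicate 4). A gene with a clone name, Fabp4, Ear2, Por, Cyp2c67 and G6pdx passed but lost the threshold in 6 to 17 refits. Fatty acid synthesis genes were lower (median −0.43, 1 of 20 called, 3 adjusted over the list alone; camera adjusted p = 0.00353; adjusted p = 0.835 with an estimated correlation). Urea cycle and amino acid genes (−0.16, 0 rose and 1 of 21 fell) and hepatocyte markers (−0.14, 0 rose and 1 of 10 fell) were lower at camera adjusted p = 0.0391. Gluconeogenesis genes (0.09, 0 of 15 called, camera adjusted p = 0.0297), collagen genes (0.11, 2 of 21 rose, 0.0274) and mitochondrially encoded genes (0.16, 0 of 13 called, 0.00368) were higher. Adjusted over the list alone, 3 urea cycle and amino acid genes and 1 hepatocyte marker were lower and 4 collagen genes higher. With an estimated correlation these 5 lists had adjusted p of 0.662 to 0.847. Lipid droplet genes did not stand apart (median 0.08, 0 of 18 called, camera adjusted p = 0.234), nor did the remaining fixed lists.

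Settings that moved the CAST/EiJ count by over 1.5 times were DESeq2, with 321 genes, the identifier run as covariate, with 99, and a fit to this strain alone, with 77. Fits within the 3 identifier runs gave 137, 0 and 0 genes (edgeR; 1302, 647 and 799 at an unadjusted p under 0.05). Leaving out female 10% fat replicates 1, 2, 3 and 4 gave 64, 417, 93 and 53 genes, and female 44% fat replicates 1, 2, 3 and 4 gave 257, 91, 83 and 93. Male 10% fat replicates 1 and 2 gave 30 and 70, and male 44% fat replicates 2, 3 and 4 gave 96, 93 and 91.

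In NZO/HlLtJ, 4 of 18 lipid droplet genes and 8 of 16 glycolysis and fructose genes rose on the 44% fat diet, and 9 of 25 acute phase genes fell. These lists had adjusted p of 0.273, 0.273 and 0.375 with an estimated correlation. Mogat1 rose from 2.074 ± 1.41 to 9.031 ± 3.25 CPM (SD, n = 8 per diet; log2 fold change 2.15, SE 0.36, adjusted p = 3.14e-04). Cidec rose from 0.6133 ± 0.477 to 3.376 ± 2.85 CPM (2.34, SE 0.57, adjusted p = 0.0106). The microsomal epoxide hydrolase Ephx1 rose from 263.6 ± 94.7 to 495.3 ± 169 CPM (0.90, SE 0.17, adjusted p = 0.00119). Fga, a fibrinogen chain, fell from 5905 ± 1200 to 3641 ± 859 CPM (−0.71, SE 0.10, adjusted p = 2.88e-05). Apoa1, the main apolipoprotein of high-density lipoprotein, fell from 5863 ± 1710 to 3271 ± 618 CPM (−0.84, SE 0.16, adjusted p = 6.79e-04). By edgeR's quasi-likelihood test 939 genes changed, 582 higher and 357 lower, of which 303 changed by at least 1.5-fold.

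Of 18 lipid droplet genes in NZO/HlLtJ, 4 rose, and 5 when adjusted over the list alone (camera adjusted p = 1.17e-05; adjusted p = 0.273 with an estimated correlation; fry adjusted p = 0.00514). Fitm1 rose by 1.33 (SE 0.17, adjusted p = 1.44e-05), and Cidea, which promotes droplet fusion, by 3.19 (SE 0.79, adjusted p = 0.0106), from a mean of 0.04363 to 0.6462 CPM. Cidea lost the threshold with a clock score in the model or without NZO/HlLtJ female 44% fat replicate 4 (adjusted p up to 0.118). That library stood 1.01 log2 units above its group median for adipocyte markers, a list with a median diet log2 fold change of 0.51 in NZO/HlLtJ, 0 of 3 tested members called and camera adjusted p = 0.502. Of 16 glycolysis and fructose genes 8 rose, and 10 when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 2.85e-08; adjusted p = 0.273 with an estimated correlation; fry adjusted p = 0.00138). They included Eno1 (0.48, SE 0.08, adjusted p = 2.43e-04), Gapdh (0.47, SE 0.09, adjusted p = 0.00117) and the fructose-pathway enzyme Tkfc (0.57, SE 0.12, adjusted p = 0.00154). The gluconeogenic enzyme Fbp1 rose from 858.9 ± 181 to 1295 ± 223 CPM (0.58, SE 0.08, adjusted p = 8.32e-06). Its list had 2 of 15 members called and 3 adjusted over the list alone (camera adjusted p = 0.00831; adjusted p = 0.375 with an estimated correlation).

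Of the fatty acid oxidation genes 8 of 34 rose in NZO/HlLtJ, and 18 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 1.11e-11; adjusted p = 0.375 with an estimated correlation; fry adjusted p = 0.0252). Hadh (0.40, SE 0.08, adjusted p = 0.00168) and Acaa1b (0.89, SE 0.20, adjusted p = 0.00427) were among them. Of the glutathione and antioxidant genes 3 of 16 rose, and 8 adjusted over the list alone (median 0.39, camera adjusted p = 8.29e-05; adjusted p = 0.375 with an estimated correlation). Respiratory chain genes had 5 of 17 higher and 7 adjusted over the list alone (median 0.11, camera adjusted p = 5.27e-06; adjusted p = 0.375 with an estimated correlation). Oat (0.96, SE 0.20, adjusted p = 0.00214) and Asl (0.46, SE 0.10, adjusted p = 0.00424) were among 4 of 21 urea cycle and amino acid genes that rose, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00123; adjusted p = 0.411 with an estimated correlation). The fatty acid carriers Fabp4 (1.02, SE 0.22, adjusted p = 0.00362) and Cd36 (0.89, SE 0.24, adjusted p = 0.0249) rose in an uptake list with 4 members higher and 1 lower of 15 (camera adjusted p = 0.141). Cd36 lost the threshold without NZO/HlLtJ male 10% fat replicates 1, 2 or 3, male 44% fat replicate 3 or female 44% fat replicate 4 (adjusted p up to 0.0693).

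Of the acute phase genes in NZO/HlLtJ, 9 of 25 were called lower and 0 higher, with 10 lower and 1 higher adjusted over the list alone (median −0.28, camera adjusted p = 1.68e-06; adjusted p = 0.375 with an estimated correlation). Of 100 splits of the libraries 11 gave a list mean as large. Fgb (−0.68, SE 0.10, adjusted p = 5.16e-05), Fgg (−0.64, SE 0.10, adjusted p = 9.15e-05) and Itih4 (−0.48, SE 0.09, adjusted p = 9.78e-04) fell beside Fga. Hepatocyte markers fell in 4 of 10 cases, and in 5 with 1 higher adjusted over the list alone (median −0.19, camera adjusted p = 0.00282; adjusted p = 0.273 with an estimated correlation). Alb, the albumin gene, fell (−0.36, SE 0.09, adjusted p = 0.0103). Of 19 endoplasmic reticulum stress genes 3 fell, and 10 adjusted over the list alone (median −0.43, camera adjusted p = 6.84e-06; adjusted p = 0.375 with an estimated correlation), among them the chaperone cofactor Sdf2l1 (−1.42, SE 0.32, adjusted p = 0.00482).

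Further NZO/HlLtJ lists passed camera with few called members. Cholesterol synthesis genes were lower (median −0.22, 1 of 24 fell, camera adjusted p = 0.0014; adjusted p = 0.597 with an estimated correlation), Tm7sf2 being the called member (−0.65, SE 0.15, adjusted p = 0.00505). NZO/HlLtJ male 44% fat replicate 1 stood 1.4 log2 units below its group median for this list, and 37 of 100 splits gave a list mean as large. Interferon genes (−0.17, 1 of 22 fell, camera adjusted p = 0.00979), male-biased liver genes (−0.20, 2 of 20 fell, 0.00391), T and NK cell markers (−0.41, 0 of 12 called, 0.0357) and B and plasma cell markers (−0.41, 0 of 10 called, 0.0495) were lower. Collagen genes (0.40, 2 of 21 rose, 3.77e-04), cell cycle genes (0.35, 2 of 20 rose, 0.00754), fatty acid synthesis genes (0.45, 1 of 20 rose, 0.0222) and mitochondrially encoded genes (0.20, 0 of 13 called, 0.00159) were higher. For cell cycle genes NZO/HlLtJ female 44% fat replicate 2 stood 1.33 and male 10% fat replicate 4 stood 1 log2 unit above the group median. Adjusted over the list alone, male-biased genes had 2 members lower and 1 higher, cell cycle genes 3 higher and mitochondrially encoded genes 2 higher. With an estimated correlation these 8 lists had adjusted p of 0.375 to 0.673, and the remaining fixed lists did not pass camera.

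Among single genes with the largest changes in NZO/HlLtJ, the laminin chain Lamb3 rose from 3.772 ± 1.2 to 10.11 ± 2.37 CPM (1.41, SE 0.18, adjusted p = 8.32e-06). Smpd3 (1.84, SE 0.38, adjusted p = 0.00225), Nnmt, a nicotinamide methyltransferase (1.46, SE 0.32, adjusted p = 0.0035), and the galectin Lgals1 (1.41, SE 0.24, adjusted p = 3.50e-04) also rose. Socs2, a feedback inhibitor of growth hormone signalling, fell from 23.28 ± 12.2 to 8.368 ± 5.71 CPM (−1.61, SE 0.39, adjusted p = 0.0103). The vasopressin receptor Avpr1a (−1.10, SE 0.21, adjusted p = 9.95e-04) and Gcnt4 (−1.09, SE 0.18, adjusted p = 2.10e-04) fell. These 7 passed in all 23 refits. The antisense gene Ctcflos (2.03, adjusted p = 7.34e-05) and Serpina1e (−2.42, adjusted p = 0.0114), a member of a family with near-identical copies, are uncertain because reads may be shared. Krt23 (1.65, adjusted p = 0.0152; 0.0517 without NZO/HlLtJ female 44% fat replicate 4) and Gsta2 (1.58, adjusted p = 0.0213; 0.0609 without male 44% fat replicate 1) rose. E2f8 fell (−1.05, adjusted p = 0.0213; up to 0.0531 without female 44% fat replicate 2 or male 10% fat replicate 2). Gdf15, Cyp2a22, Eci3, Fabp5, Enho, Hamp2 and Smad9 passed but lost the threshold in 7 to 17 refits.

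The NZO/HlLtJ count fell to 532 without male 10% fat replicate 2 and to 613 without female 44% fat replicate 4. Within identifier run 1 alone 8 genes passed (edgeR; 1831 at an unadjusted p under 0.05), and runs 2 and 3 did not hold both diets in both sexes.

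Whether the diet response differs between strains was tested directly, as strain-by-diet interaction. Few genes passed. Ddah1, which degrades the nitric oxide synthase inhibitor dimethylarginine (ENSMUSG00000028194, chromosome 3: 145758675 to 145894277), changed in NZO/HlLtJ by a log2 fold change of 1.27, against 0.03 in C57BL/6J and 0.01 in CAST/EiJ (adjusted p = 1.36e-04 over the 3 strains). Tstd1 (ENSMUSG00000103711, chromosome 1: 171418872 to 171420352) had 0.66 in C57BL/6J, −0.66 in CAST/EiJ and −0.82 in NZO/HlLtJ (adjusted p = 9.61e-05), and Tceal8 (ENSMUSG00000051579, chromosome X: 136168984 to 136172342) had 0.60, −0.63 and 0.54 (adjusted p = 4.38e-04).

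The joint test in edgeR called 8 genes (1758 at an unadjusted p under 0.05). Beside those 3 they included Mmd2 (1.77, −0.16 and 1.04 in C57BL/6J, CAST/EiJ and NZO/HlLtJ; adjusted p = 0.0053) and the stress kinase Zak (0.16, −0.33 and 0.63; adjusted p = 0.0053). The steroid hydroxylase Cyp17a1 also passed (0.75, −1.06 and 1.04; adjusted p = 0.0327). Kbtbd11, of low expression (0.86, 0.47 and 2.40; adjusted p = 0.0252), falls outside the naming rule and was chosen after its values were seen. Tstd1, Ddah1, Tceal8, Zak and Mmd2 passed in all 54 refits, and Cyp17a1 lost the threshold in 18 of them (adjusted p up to 0.0817), the fit without the acinar libraries among them. Ccng1 (adjusted p = 0.055) and BC089597, Enpp2, Cyp2c44, Dpp7 and F12 (each 0.0558) came next and did not pass.

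**Figure D2:**
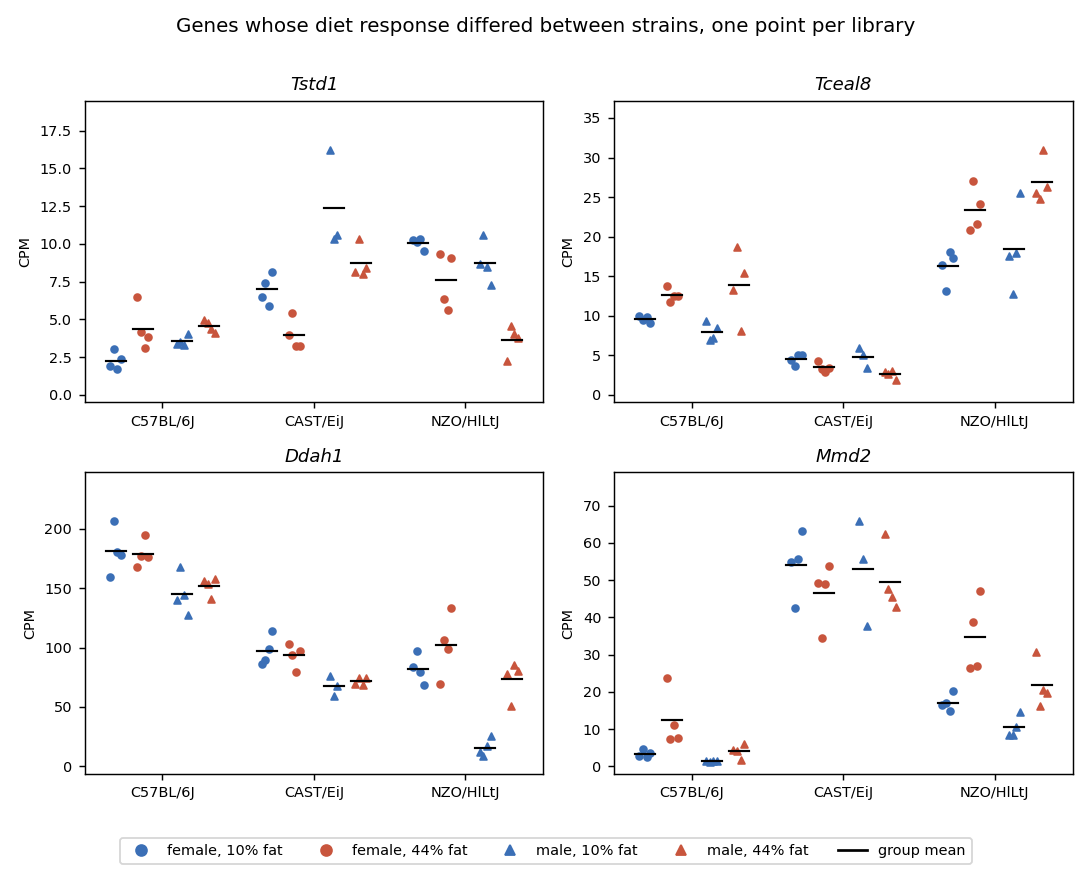
Counts per M of Tstd1, Tceal8, Ddah1 and Mmd2 in each library by strain, sex and diet, with bars at the group means. Ddah1 in NZO/HlLtJ males had means of 15.7 CPM on 10% fat and 73.69 CPM on 44% fat.

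The joint count was 146 with DESeq2 and 19 with a stricter expression filter. Without C57BL/6J female 44% fat replicates 1 and 2 it was 23 and 19, without C57BL/6J male 10% fat replicate 4 it was 25, and without male 44% fat replicate 3 it was 36. Leaving out CAST/EiJ female 44% fat replicate 1, female 10% fat replicate 2 or male 10% fat replicate 3 gave 39, 41 and 25. Leaving out NZO/HlLtJ female 44% fat replicate 1, male 44% fat replicate 1 or male 10% fat replicate 4 gave 28, 14 and 72.

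Pair by pair, the diet effect differed between NZO/HlLtJ and C57BL/6J for 2 genes, Ddah1 (difference in log2 fold change 1.24, SE 0.19, adjusted p = 5.50e-04) and Tstd1 (−1.49, SE 0.20, adjusted p = 1.17e-04). Between CAST/EiJ and C57BL/6J it differed for 3, Mmd2 (−1.93, SE 0.32, adjusted p = 0.00283), Tceal8 (−1.23, SE 0.19, adjusted p = 0.00102) and Tstd1 (−1.33, SE 0.21, adjusted p = 0.00102). Without the acinar libraries Ddah1 was not called between NZO/HlLtJ and C57BL/6J (1.16, SE 0.22, adjusted p = 0.0508), nor Mmd2 (−1.63, SE 0.32) and Tceal8 (−1.12, SE 0.23) between CAST/EiJ and C57BL/6J (adjusted p = 0.0735 for both), while Tstd1 passed in both. Between NZO/HlLtJ and CAST/EiJ it differed for 18, 14 higher in NZO/HlLtJ and 4 lower, among them Cyp17a1 (2.09, SE 0.42, adjusted p = 0.0244), Zak (0.96, adjusted p = 0.0014), Ddah1 (1.26, adjusted p = 0.00113) and the collagen gene Col5a3 (1.56, adjusted p = 0.0312). The Cyp17a1 difference reached adjusted p = 0.0918 at most, and did not pass without CAST/EiJ male 10% fat replicate 1, CAST/EiJ female 44% fat replicate 2, NZO/HlLtJ male 10% fat replicate 2 or NZO/HlLtJ male 44% fat replicate 3. The edgeR test gave 1172, 1594 and 1731 genes at an unadjusted p under 0.05, and DESeq2 called 35, 71 and 134. The 3 pairwise tests share libraries.

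These pairwise counts moved with single libraries. The NZO/HlLtJ against C57BL/6J count became 13, 5 and 7 without C57BL/6J female 44% fat replicates 1 and 3 and male 44% fat replicate 3. It became 7, 4 and 15 without NZO/HlLtJ female 44% fat replicate 1, male 44% fat replicate 3 and male 10% fat replicate 4. The CAST/EiJ against C57BL/6J count became 9, 24, 5, 5 and 5 without CAST/EiJ female 44% fat replicate 1, female 10% fat replicates 2 and 3 and male 10% fat replicates 2 and 3. It became 7, 7 and 20 without C57BL/6J female 44% fat replicate 2, male 10% fat replicate 4 and male 44% fat replicate 3, and 1 without the acinar libraries. The NZO/HlLtJ against CAST/EiJ count became 31 and 7 without CAST/EiJ female 44% fat replicates 1 and 2, and 36 and 10 without CAST/EiJ female 10% fat replicates 2 and 3. It became 10 and 34 without CAST/EiJ male 10% fat replicates 1 and 3, and 10 without CAST/EiJ male 44% fat replicate 2. It became 38 and 11 without NZO/HlLtJ female 44% fat replicates 1 and 3, and 11 without female 10% fat replicate 3. It became 6 and 82 without male 10% fat replicates 2 and 4, and 11 without male 44% fat replicate 3. It was 11 with the identifier run and 31 with a clock score in the model.

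As a group, cholesterol synthesis genes responded lower in CAST/EiJ than in C57BL/6J, with a median difference of −0.97 (camera adjusted p = 3.79e-15; adjusted p = 0.777 with an estimated correlation). Of the 24 genes 0 were called over all genes and 14 were lower adjusted over the list alone. Sqle (−2.14, SE 0.57, adjusted p = 0.164) and Dhcr7 (−1.44, SE 0.37, adjusted p = 0.162) did not pass singly, nor did Hamp (−6.04, SE 1.32, adjusted p = 0.089). Fatty acid synthesis genes differed in the same direction (median −0.75, 0 of 20 called and 6 lower adjusted over the list alone, camera adjusted p = 1.48e-05; adjusted p = 0.777 with an estimated correlation). Between NZO/HlLtJ and CAST/EiJ, cholesterol synthesis genes differed by a median of 0.67 (camera adjusted p = 2.51e-05) and endoplasmic reticulum stress genes by −0.46 (3.92e-06), with 0 and 6 genes apart adjusted over the list alone, and both with adjusted p = 0.533 with an estimated correlation. Between NZO/HlLtJ and C57BL/6J, interferon genes differed by −0.35 (camera adjusted p = 6.43e-09) and acute phase genes by −0.38 (1.76e-06), with 5 and 5 genes lower adjusted over the list alone, and both with adjusted p = 0.415 with an estimated correlation. Camera called 14 lists for NZO/HlLtJ against C57BL/6J, 10 for CAST/EiJ against C57BL/6J and 12 for NZO/HlLtJ against CAST/EiJ, and 0 in each pair with an estimated correlation.

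The genes called by diet overlapped between strains whose contrasts share no libraries. C57BL/6J and NZO/HlLtJ shared 73 genes called higher, where 4.8 would be shared by independent lists, and 10 called lower (0.6), with 1 in opposite directions. CAST/EiJ and NZO/HlLtJ shared 27 higher (2.9) and 7 lower (1.4), with 2 opposite, and C57BL/6J and CAST/EiJ 5 higher (0.7) and 1 lower (0.1), with 2 opposite. Over all 16650 genes, which are not independent replicates, diet log2 fold changes correlated at r = 0.275, 0.102 and 0.082 for these pairs. Genes called in all 3 strains were Gpc1 (1.07, 1.01 and 1.24 in C57BL/6J, CAST/EiJ and NZO/HlLtJ), Them7 (0.81, 0.51 and 0.63), the ammonium transporter Rhbg (0.64, 0.61 and 0.76), Slco2a1 (−0.58, −0.59 and −0.63), Gfm2 (0.19, 0.21 and 0.23), Tceal8 and Tstd1, the last pair in differing directions. Gfm2 and Rhbg were chosen after their values were seen.

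Genes chosen in advance for lipid and glucose metabolism, inflammation and fibrosis mostly did not pass a diet test. Fasn, the fatty acid synthase, had 0.27, −1.19 and 0.47 in C57BL/6J, CAST/EiJ and NZO/HlLtJ (adjusted p = 0.849, 0.153 and 0.549), and Scd1 had 0.52, −0.73 and 0.57 (0.618, 0.46 and 0.418). Trem2, a marker of lipid-associated macrophages, had 1.06, 0.48 and 0.34 (adjusted p = 0.353, 0.859 and 0.783), and Col1a1 had 0.94, 0.06 and 0.72 (0.192, 0.986 and 0.228). Srebf1, Cyp7a1, Pck1, Igfbp1, Fgf21, Cpt1a and Saa1 did not pass in any strain either, Pck1 with adjusted p = 0.868, 0.584 and 0.216. Cd36 was 0.88 in C57BL/6J (adjusted p = 0.0726) and 0.10 in CAST/EiJ (0.942), and Cidec 0.99 in CAST/EiJ (0.505).

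Whether the diet response differs between the sexes was tested within each strain. In NZO/HlLtJ, Ddah1 stood at 15.7 ± 7.35 CPM in males on 10% fat and 73.69 ± 15.5 CPM in males on 44% fat (SD, n = 4), and at 82.21 ± 12 and 102.1 ± 26.5 CPM in females (difference in log2 fold change 1.92, SE 0.27, adjusted p = 1.92e-04 by edgeR). Foxq1, a forkhead transcription factor (chromosome 13: 31558324 to 31560976), went from 35.49 ± 20.3 to 2.926 ± 0.346 CPM in males and from 6.893 ± 3.16 to 15.29 ± 5.85 CPM in females (−4.76, SE 0.80, adjusted p = 0.00718). Hao2, a peroxisomal hydroxyacid oxidase (3.69, SE 0.67, adjusted p = 0.0152), was the third gene; it lies outside the naming rule and was chosen after its values were seen. With the identifier run as covariate Hao2 was not called, with a smaller difference and a larger error (3.39, SE 0.75, adjusted p = 0.261). Ddah1 and Foxq1 passed in all 23 refits. Outside run 1, NZO/HlLtJ females on 10% fat and males on 44% fat were in run 2 and the other NZO/HlLtJ groups in run 3, so there this comparison coincides with the run. In the 8 libraries of run 1 alone, the difference in mean log2 CPM was 2.71 for Ddah1, −4.31 for Foxq1 and 2.28 for Hao2, against 2.03, −4.56 and 3.09 in all 3 runs.

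Cholesterol synthesis genes in NZO/HlLtJ responded lower in males than in females by a median of −1.05 (0 of 24 called, 6 lower adjusted over the list alone; camera adjusted p = 3.06e-19; adjusted p = 0.291 with an estimated correlation). Fatty acid synthesis genes differed by −1.40 (0 of 20 called, 12 lower adjusted over the list alone; 1.64e-18; adjusted p = 0.261 with an estimated correlation). Fatty acid oxidation genes differed by 0.44 (0 of 34 called, 9 higher adjusted over the list alone; 9.00e-14; adjusted p = 0.381 with an estimated correlation). NZO/HlLtJ male 44% fat replicate 1, the library with the fewest counts (21.6 M), stood 1.4 log2 units below its group median for cholesterol synthesis and 1.43 below for fatty acid synthesis, and replicate 3 stood 1 above for fatty acid synthesis. In females and males respectively, Fasn had diet log2 fold changes of 1.56 and −0.62, and Sqle of 0.19 and −1.82, neither called for this difference. Camera called 13, 7 and 9 lists for sex-by-diet in C57BL/6J, CAST/EiJ and NZO/HlLtJ, and 0 in each with an estimated correlation.

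In C57BL/6J, 14 genes differed by sex in their diet response, all 14 lower in males, and all of low average expression (at most 0.1 log2 CPM). They were digestive enzyme genes and companions, named after their values were seen: Cpa1, Ctrb1, Pnlip and Cela2a of the acinar list, 5 Amy2a genes that share reads, and Ctrl, Pnliprp1, Tff2, Dmbt1 and Klk1. The 4 C57BL/6J libraries with Cpa1 of at least 20 CPM were 2 females on 44% fat and 2 males on 10% fat, another female on 44% fat had 12.2 CPM, and without the acinar libraries 1 gene was called, 0 of them among the 14. Stellate cell and collagen genes also differed (median −0.91, 0 of 21 called and 10 lower adjusted over the list alone; camera adjusted p = 4.94e-07; adjusted p = 0.538 with an estimated correlation). So did endoplasmic reticulum stress genes (−0.80, 0 of 19 called; 5.81e-09; adjusted p = 0.333 with an estimated correlation). As above, collagen genes stood high in C57BL/6J female 44% fat replicate 1. In CAST/EiJ edgeR called 0 genes (669 at an unadjusted p under 0.05) and DESeq2 14.

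**Figure D3:**
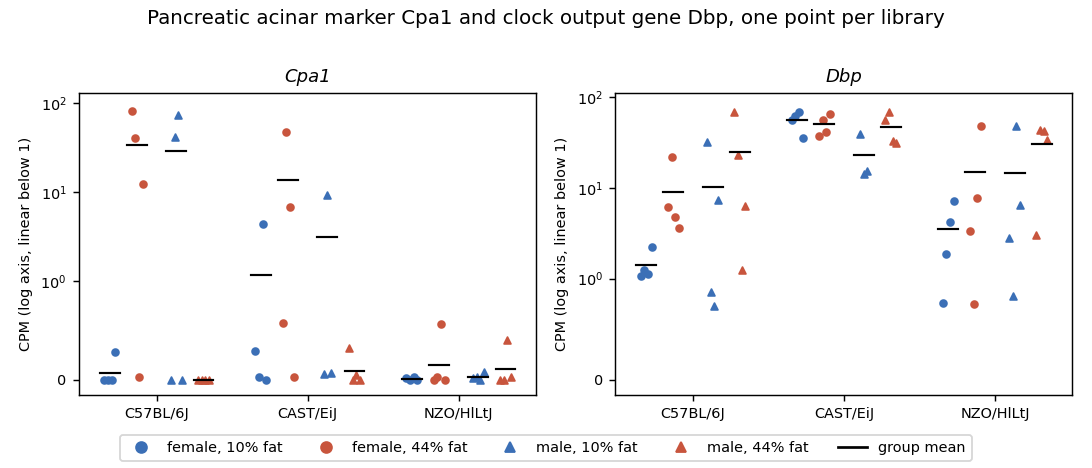
Counts per M of the acinar marker Cpa1 and the clock output gene Dbp in each library by strain, sex and diet, on a log axis that is linear below 1. The 5 libraries with Cpa1 from 41 to 81 CPM stand above all others, whose highest value is 12.2 CPM, and median Dbp in CAST/EiJ is 41.6 CPM, against 4.2 in C57BL/6J and 5.4 in NZO/HlLtJ.

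The sex-by-diet counts were small and moved with single libraries. In C57BL/6J the count fell to 3, 7, 3 and 5 without female 10% fat replicates 1, 2, 3 and 4. It fell to 6 without any of male 44% fat replicates 1, 2, 3 and 4, to 5 without male 10% fat replicate 3, to 6 with a clock score, and to 0 with this strain alone. In CAST/EiJ it was 3 without male 10% fat replicate 1, 4 without the acinar libraries and 1 with the strain alone. In NZO/HlLtJ it was 5 without female 44% fat replicates 1 or 4 or female 10% fat replicate 4, 7 and 18 without male 44% fat replicates 2 and 3, 14 without male 10% fat replicate 3, 9 without the acinar libraries and 41 with DESeq2.

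Within single sexes, edgeR called 17 genes by diet in C57BL/6J females (16 higher, 1 lower), 7 in C57BL/6J males (all higher), 33 in CAST/EiJ females (19 higher, 14 lower), and 2 in CAST/EiJ males (both higher). It called 81 in NZO/HlLtJ females (75 higher, 6 lower) and 446 in NZO/HlLtJ males (259 higher, 187 lower). DESeq2 called 122, 73, 82, 32 and 228 in the first 5 of these. In C57BL/6J females the count was 7, 11, 9 and 11 without 10% fat replicates 1, 2, 3 and 4, 95, 53 and 116 without 44% fat replicates 2, 3 and 4, and 2 with the strain alone. C57BL/6J males had 0, 0 and 21 without 10% fat replicates 2, 3 and 4. They had 4, 0, 136 and 0 without 44% fat replicates 1, 2, 3 and 4, 0 without the acinar libraries and 0 with the strain alone (1457 at an unadjusted p under 0.05 in the full edgeR fit). CAST/EiJ females had 10, 163, 10 and 6 without 10% fat replicates 1, 2, 3 and 4, 61, 20 and 8 without 44% fat replicates 1, 2 and 4, and 21 with the strain alone. CAST/EiJ males had 4, 0 and 8 without 10% fat replicates 1, 2 and 3, 8 without the acinar libraries and 5 with the strain alone (1219 at an unadjusted p under 0.05 in the full fit). NZO/HlLtJ females had 48, 37, 35 and 28 without 10% fat replicates 1, 2, 3 and 4, 172, 23, 34 and 17 without 44% fat replicates 1, 2, 3 and 4, 187 without the acinar libraries and 50 with the identifier run. NZO/HlLtJ males had 227, 103 and 239 without 10% fat replicates 1, 2 and 3, and 242 and 139 without 44% fat replicates 1 and 4.

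Strains differed far more than diets. Averaged over sexes and diets, Akr1c18, a steroid-reducing aldo-keto reductase, stood at 0.142 ± 0.151 CPM in C57BL/6J (SD, n = 16), 85.4 ± 33.3 CPM in NZO/HlLtJ (n = 16; 601-fold, adjusted p = 1.53e-34) and 154 ± 21.8 CPM in CAST/EiJ (n = 15; 1080-fold, adjusted p = 1.93e-36). Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, stood at 0.295 ± 0.113 CPM in NZO/HlLtJ, against 42.9 ± 14 CPM in C57BL/6J (adjusted p = 1.29e-33) and 94.3 ± 55.2 CPM in CAST/EiJ (adjusted p = 1.27e-35). Iigp1, an interferon-inducible GTPase, stood at 0.0478 ± 0.0757 CPM in CAST/EiJ, against 323 ± 47.6 CPM in C57BL/6J (adjusted p = 1.41e-39) and 315 ± 57.3 CPM in NZO/HlLtJ (adjusted p = 2.14e-39). H2-Q7 stood at 3.38 ± 0.745 CPM in NZO/HlLtJ and 66.1 ± 9.42 CPM in C57BL/6J (adjusted p = 3.01e-31).

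By edgeR, 8172 genes differed between NZO/HlLtJ and C57BL/6J (4246 higher and 3926 lower in NZO/HlLtJ), 11299 between CAST/EiJ and C57BL/6J (5428 higher and 5871 lower in CAST/EiJ), and 11336 between NZO/HlLtJ and CAST/EiJ (5874 higher and 5462 lower in NZO/HlLtJ). Of these 3053, 5758 and 5675 differed by at least 1.5-fold. Reads of CAST/EiJ and NZO/HlLtJ differ in sequence from the reference genome, so part of these differences may come from how reads were assigned. Other leading genes belong to families with near-identical copies and are uncertain: Mup15, Mup17, Mup18 and Mup20 of the major urinary proteins, Cyp2c39, Cyp3a41a and Cyp3a41b, Sult3a1, Hamp2, Pgk1-rs7, Rpl9-ps6 and Rpl19-ps11. Mup20 had 4400 CPM in C57BL/6J, 137 CPM in NZO/HlLtJ and 0.0421 CPM in CAST/EiJ. Sult3a1 had 22, 81.7 and 1740 CPM in C57BL/6J, NZO/HlLtJ and CAST/EiJ, and Hamp2 had 91.7 CPM in C57BL/6J, 525 CPM in NZO/HlLtJ and 3 counts in all CAST/EiJ libraries.

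Gene groups that stood apart in CAST/EiJ against C57BL/6J were cholesterol synthesis, 19 of 24 lower and 1 higher (median −1.14, camera adjusted p = 7.43e-04), fatty acid oxidation, 24 of 34 lower (−0.55, 2.70e-05), interferon response, 19 of 22 lower and 2 higher (−1.59, 3.90e-06), and Kupffer cell markers, 12 of 14 lower and 1 higher (−0.96, 8.88e-04). Also apart were urea cycle and amino acid genes, 16 of 21 higher and 1 lower (0.55, 8.88e-04), and respiratory chain genes, 13 of 17 higher and 2 lower (0.29, 4.45e-04). Each of these 6 had adjusted p = 0.964 with an estimated correlation. T and NK cell markers were lower in 10 of 12 cases and higher in 1 (−2.54, 0.00493; adjusted p = 0.947 with an estimated correlation). Adjusted over the list alone these counts were the same. NZO/HlLtJ stood above CAST/EiJ in cholesterol synthesis, 23 of 24 (median 1.30, camera adjusted p = 1.62e-05), fatty acid oxidation, 28 of 34 (0.52, 1.62e-05), and interferon response, 19 of 22 with 3 lower (1.74, 1.44e-06), each with adjusted p = 0.871 with an estimated correlation. Camera called 7 lists for CAST/EiJ against C57BL/6J and 12 for NZO/HlLtJ against CAST/EiJ, and 0 in each with an estimated correlation. Against C57BL/6J, NZO/HlLtJ differed in 1 list, urea cycle and amino acid genes, with 14 of 21 higher and 0 lower, or 14 and 1 adjusted over the list alone (0.24, camera adjusted p = 0.00739; adjusted p = 0.988 with an estimated correlation).

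Sex differences followed the known sex-dimorphic liver genes in every strain. Cyp4a12a, a male-specific fatty acid hydroxylase, had 447 ± 115 CPM in C57BL/6J males and 0.453 ± 0.881 CPM in females (SD, n = 8; 987-fold, adjusted p = 4.57e-17). It had 779 ± 82.2 CPM (n = 7) and 1.67 ± 2.13 CPM in CAST/EiJ, and 880 ± 124 and 1.24 ± 1.54 CPM in NZO/HlLtJ. The fatty acid elongase Elovl3 was 95.9-fold higher in C57BL/6J males and 319-fold higher in CAST/EiJ males. C6, a complement component, stood at 2280 ± 490 CPM in CAST/EiJ males and 21.6 ± 6.01 CPM in females (adjusted p = 3.53e-20), and Selenbp2 at 2530 ± 160 and 18.2 ± 7.82 CPM. Higher in females were Cyp3a44, by 1810-fold in C57BL/6J, 488-fold in CAST/EiJ and 446-fold in NZO/HlLtJ, Slc22a26, by 1150-fold in CAST/EiJ, and Cyp2a4, by 119-fold in NZO/HlLtJ. Cyp3a41a had 0 counts in C57BL/6J males and 922 ± 689 CPM in females, at least 100000-fold higher against a floor of 3 counts over the group. The cytochrome, Mup and Sult families hold near-identical copies, so single members are uncertain.

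By edgeR, 2797 genes differed by sex in C57BL/6J (1348 higher and 1449 lower in males), 5050 in CAST/EiJ (2682 and 2368) and 2872 in NZO/HlLtJ (1322 and 1550), of which 1094, 2046 and 1290 differed by at least 1.5-fold. The list of female-biased liver genes was lower in males for 18 of 18 members in C57BL/6J, 16 of 18 in CAST/EiJ and 18 of 18 in NZO/HlLtJ, the same counts as adjusted over the list alone. It held with an estimated correlation (adjusted p = 5.35e-07, 5.85e-04 and 2.56e-06). Male-biased liver genes were higher for 19, 18 and 19 of 20 members (20, 18 and 20 adjusted over the list alone). They also held with an estimated correlation (adjusted p = 3.07e-06, 0.00604 and 2.21e-05). Xenobiotic cytochromes were lower in CAST/EiJ males for 13 of 20 members and higher for 2, or 14 and 2 adjusted over the list alone (camera adjusted p = 5.51e-10; adjusted p = 0.0316 with an estimated correlation).

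Macrophage and Kupffer cell markers were lower in males in all 3 strains, with 8 of 14 members in C57BL/6J (camera adjusted p = 6.56e-05), 13 of 14 in CAST/EiJ with 1 higher (1.29e-07) and 12 of 14 in NZO/HlLtJ (4.22e-07). Adjusted over the list alone they were 10, 13 and 12 (adjusted p = 0.482, 0.319 and 0.255 with an estimated correlation). Interferon response genes were lower in males for 10 of 22 members in C57BL/6J (camera adjusted p = 1.64e-06; adjusted p = 0.482 with an estimated correlation) and 12 of 22 in NZO/HlLtJ (1.02e-05; adjusted p = 0.356 with an estimated correlation), or 12 and 14 adjusted over the list alone. In CAST/EiJ, 21 of 34 fatty acid oxidation genes were lower in males, and 24 adjusted over the list alone (camera adjusted p = 7.87e-13; adjusted p = 0.319 with an estimated correlation). Acute phase genes were lower in males for 9, 13 and 8 of 25 members in C57BL/6J, CAST/EiJ and NZO/HlLtJ and higher for 0, 2 and 1 (camera adjusted p = 8.52e-05, 3.89e-05 and 0.00501; adjusted p = 0.482, 0.457 and 0.522 with an estimated correlation). Adjusted over the list alone, 10, 14 and 9 acute phase genes were lower. Camera called 15, 12 and 18 lists by sex in C57BL/6J, CAST/EiJ and NZO/HlLtJ, and 2, 3 and 2 with an estimated correlation.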

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

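Single libraries stood apart from their group for several of the genes chosen in advance, by Dixon's test within each group on log2 CPM. The test marked 18 of 198 combinations of group and quantity, where chance marks about 5%. In C57BL/6J females on 44% fat, replicate 1 had Col1a1 at 81.6 CPM (other libraries of the group 6.42 to 8.52), Fasn at 646 CPM (1690 to 1780) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 15.2 CPM (57.1 to 74.9), and replicate 2 had Cidea at 0 CPM (0.0676 to 0.0746). Replicate 3 of the C57BL/6J females on 10% fat had Trem2 at 0.198 CPM (0.404 to 0.445). Among C57BL/6J males on 44% fat, replicate 4 had 43.4 M counts (40.7 to 41.1), replicate 2 had Cyp7a1 at 44.3 CPM (76.6 to 83.6) and replicate 3 had Cidec at 1.13 CPM (8.72 to 9.56).

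In CAST/EiJ females on 44% fat, replicate 1 had 2.08% of counts in 18S ribosomal RNA (2.22 to 2.24) and Srebf1, the lipogenic transcription factor, at 431 CPM (285 to 302). Cidea was at 0.0875 CPM in replicate 2 of that group, at 0.026 CPM in CAST/EiJ female 10% fat replicate 4 and at 0.0449 CPM in CAST/EiJ male 44% fat replicate 3, with 0 in the other libraries of each group. These values are 3, 1 and 2 counts, and with 0 in all others any value above 0 is marked, so these 3 of the 18 marks say nothing about the libraries. The Cidea mark in C57BL/6J rests on at most 3 counts. In NZO/HlLtJ females on 10% fat, Trem2 was 1.9 CPM in replicate 3 (0.149 to 0.221). In NZO/HlLtJ females on 44% fat, Pck1 was 703 CPM in replicate 2 (1180 to 1260) and Scd1 7030 CPM in replicate 1 (29700 to 39000). In NZO/HlLtJ males on 10% fat, Srebf1 was 536 CPM in replicate 3 (275 to 284) and Fasn 6250 CPM in replicate 4 (2480 to 2630). Each library was kept.

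Diet responses that differ between groups were few by edgeR. The strain-by-diet tests called 2 genes for NZO/HlLtJ against C57BL/6J, 3 for CAST/EiJ against C57BL/6J and 18 for NZO/HlLtJ against CAST/EiJ, and 8 jointly over the 3 strains. The sex-by-diet tests called 14 genes in C57BL/6J and 3 in NZO/HlLtJ. The genes named for the joint test had adjusted p as follows: Tstd1 (9.61e-05), Ddah1 (1.36e-04), Tceal8 (4.38e-04), Mmd2 (0.0053), Zak (0.0053) and Cyp17a1 (0.0327). Male and female NZO/HlLtJ differed in the diet response of Ddah1 by a log2 fold change of 1.92 and of Foxq1 by −4.76.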

How the results depend on the processing

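Counts of genes changed by diet depended on the model and on single libraries in every strain, and the cause was not tested. No paired analysis was possible because the replicate numbers follow the order of the sample records only. Fits within identifier runs, of single strains and of single sexes rest on few libraries. Among genes called by the named comparisons, DESeq2 kept 202 of 203 calls, the identifier run kept 188, the fit without the acinar libraries 179 and the clock score 171 of 204, and leaving out single libraries kept 3366 of 3882. Of these calls 0 reversed direction. The clock score kept 81 of the 165 C57BL/6J genes, 105 of the 149 CAST/EiJ genes and 677 of the 939 NZO/HlLtJ genes.

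DESeq2 called 320 genes by diet in C57BL/6J, 321 in CAST/EiJ, 122 in C57BL/6J females, 73 in C57BL/6J males, 82 in CAST/EiJ females, 32 in CAST/EiJ males and 228 in NZO/HlLtJ females. For strain-by-diet it called 35 for NZO/HlLtJ against C57BL/6J, 71 for CAST/EiJ against C57BL/6J, 134 for NZO/HlLtJ against CAST/EiJ and 146 jointly, and for sex-by-diet 14 in CAST/EiJ and 41 in NZO/HlLtJ. The stricter filter gave 19 joint calls. With the identifier run as covariate CAST/EiJ had 99 diet genes, NZO/HlLtJ females 50, and NZO/HlLtJ against CAST/EiJ 11.

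Without the acinar libraries the diet counts were 61 in C57BL/6J, 0 in C57BL/6J males, 8 in CAST/EiJ males and 187 in NZO/HlLtJ females. CAST/EiJ against C57BL/6J kept 1, and sex-by-diet had 1 in C57BL/6J, 4 in CAST/EiJ and 9 in NZO/HlLtJ. With the clock score as covariate C57BL/6J had 87 diet genes and 6 sex-by-diet genes, and NZO/HlLtJ against CAST/EiJ had 31.

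A fold of at least 1.5 left 66, 68 and 303 diet genes in C57BL/6J, CAST/EiJ and NZO/HlLtJ and 243 in NZO/HlLtJ males, 1094, 2046 and 1290 sex genes, and 3053, 5758 and 5675 strain genes for NZO/HlLtJ against C57BL/6J, CAST/EiJ against C57BL/6J and NZO/HlLtJ against CAST/EiJ. Libraries of C57BL/6J alone gave 4 diet genes, 2 in females, 0 in males and 0 for sex-by-diet. Libraries of CAST/EiJ alone gave 77, 21, 5 and 1. Within identifier runs 1, 2 and 3, C57BL/6J had 3, 70 and 0, CAST/EiJ had 137, 0 and 0, and NZO/HlLtJ had 8 in run 1. The genes most changed in the other runs kept their sign in 66.5%, 72.5% and 76% of cases in C57BL/6J, 87%, 81% and 92.5% in CAST/EiJ, and 89% in run 1 of NZO/HlLtJ.

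Limma on the deposited variance-stabilized values called 145, 177 and 997 diet genes in C57BL/6J, CAST/EiJ and NZO/HlLtJ, with 73.8%, 67.2% and 63.2% higher on 44% fat, against 83%, 55.7% and 62% by edgeR. RLE factors gave 159, 148 and 938. With an estimated correlation 0, 0 and 0 gene lists passed by diet, and with fry 0, 2 and 9.

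With 1 library left out, lowest to highest, diet counts ran from 56 to 369 in C57BL/6J, 30 to 417 in CAST/EiJ and 532 to 1178 in NZO/HlLtJ. Strain-by-diet ran from 2 to 15 for NZO/HlLtJ against C57BL/6J, 3 to 24 for CAST/EiJ against C57BL/6J, 6 to 82 for NZO/HlLtJ against CAST/EiJ and 6 to 72 jointly. Sex-by-diet ran from 3 to 17 in C57BL/6J, 0 to 3 in CAST/EiJ and 2 to 18 in NZO/HlLtJ. Diet within 1 sex ran from 7 to 116 in C57BL/6J females, 0 to 136 in C57BL/6J males, 6 to 163 in CAST/EiJ females, 0 to 8 in CAST/EiJ males, 17 to 172 in NZO/HlLtJ females and 103 to 583 in NZO/HlLtJ males. Lists called by diet in CAST/EiJ ran from 4 to 12, the lowest without female 44% fat replicate 3.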

Other observations

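The larger diet count of NZO/HlLtJ, clock genes in CAST/EiJ and sex-biased genes in NZO/HlLtJ males are the patterns weighed here, and the fit without the acinar libraries, the fit with a clock score and the Xist comparison were chosen only after the results were seen. Dbp, a clock output gene, had a median of 41.6 CPM in CAST/EiJ, against 4.2 CPM in C57BL/6J and 5.4 CPM in NZO/HlLtJ. Arntl, a core activator of the clock, had 8.1 CPM in CAST/EiJ, against 23.5 and 23.1 CPM. Medians of Dbp on 10% and 44% fat were 4.66 and 37.79 CPM in NZO/HlLtJ males, 3.05 and 5.6 in NZO/HlLtJ females, 1.18 and 5.46 in C57BL/6J females, 4.16 and 14.76 in C57BL/6J males, 15.23 and 44.18 in CAST/EiJ males, and 58.05 and 48.95 in CAST/EiJ females, the only fall. With the clock score as covariate 81 of 165 diet genes (49.1%) were still called in C57BL/6J and 286 of 446 in NZO/HlLtJ males. In C57BL/6J female 44% fat replicate 1, recruited macrophage markers stood 2.49 log2 units above the group median, cell cycle genes 2.21, collagen genes 1.66 and glutathione genes 1.36, while female-biased genes stood 2.4 and xenobiotic cytochromes 1.35 below. In C57BL/6J male 10% fat replicate 2, male-biased genes stood 1.45 below the median of their group and female-biased genes 1.12 above. In NZO/HlLtJ male 44% fat replicate 1, cholesterol synthesis genes stood 1.4 and fatty acid synthesis genes 1.43 below. Female-biased genes stood 1.46 above in NZO/HlLtJ male 44% fat replicate 3 and 1.13 above in male 10% fat replicate 4, and male-biased genes 1.16 above in male 44% fat replicate 2. For the sex-biased sets weighed last, the female-biased minus the male-biased median diet log2 fold change was also toward the other sex in females. It was −0.53, −0.25 and −0.15 in C57BL/6J, CAST/EiJ and NZO/HlLtJ females, and −0.03 in C57BL/6J and CAST/EiJ males.

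Chance as a source of the counts was tested, as planned before the data were examined, by regrouping the same libraries. For diet, 1 of 100 splits, the real one, reached the count in each strain. C57BL/6J had 165 genes (highest other split 13), CAST/EiJ 149 (30) and NZO/HlLtJ 939 (57). Splits regroup all strains at once, so diet effects add to their spread. Chance is not likely over all strains together, but is undecided for each. For sex, 1 of 100 splits reached each count, with 2797 genes in C57BL/6J (highest other 468), 5050 in CAST/EiJ (2215) and 2872 in NZO/HlLtJ (140). For strain, 1 of 50 splits reached each count, with 8172 genes for NZO/HlLtJ against C57BL/6J (33), 11299 for CAST/EiJ against C57BL/6J (1068) and 11336 for NZO/HlLtJ against CAST/EiJ (4179). Large other splits can keep much of the real labels or follow other structure, which was not tested.

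For differences in diet response between strains, these splits also break up the main diet effect, so they leave chance undecided. For NZO/HlLtJ against C57BL/6J 5 of 100 splits reached the 2 genes called (highest other 12). For CAST/EiJ against C57BL/6J it was 3 (3 genes, 14), for NZO/HlLtJ against CAST/EiJ 1 (18 genes, 9) and jointly 2 (8 genes, 13). Between the sexes, 2 of 100 splits reached the 14 genes of C57BL/6J (highest other 15), but these genes follow the libraries with acinar transcripts, and 0 of the 14 were called without the acinar libraries, so the count is no evidence of a sex difference in diet response. Chance cannot be excluded in CAST/EiJ (100 of 100, 0 genes, highest other 10) or NZO/HlLtJ (5 of 100, 3 genes). Another NZO/HlLtJ split called 442 genes, and its source was not tested.

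Within sexes, chance can be excluded for diet in NZO/HlLtJ females (1 of 35 splits, 81 genes, highest other 1) and males (1, 446, 43). C57BL/6J males had 7 genes (1 of 35, highest other 6) but 0 without the acinar libraries, so chance stays open. It cannot be excluded in C57BL/6J females (2 of 35, 17 genes, highest other 36), CAST/EiJ females (3, 33, 452) or males (2, 2, 2). The source of the split with 452 genes was not tested. Chance cannot be excluded for the number of gene lists called by diet. Of 100 splits 41 reached the 12 of C57BL/6J (highest other 22), 30 the 8 of CAST/EiJ (17) and 8 the 19 of NZO/HlLtJ (23).

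For the single lists called by diet with camera, a test chosen after the results were seen, splits of 100 that reached the list mean were counted. In CAST/EiJ they were 1 for cholesterol synthesis and for fatty acid oxidation, 2 for hepatocyte markers, 4 for fatty acid synthesis, 5 for collagen, 7 for gluconeogenesis and for mitochondrially encoded genes, and 14 for urea cycle and amino acid genes. In NZO/HlLtJ they were 1 for lipid droplets, glycolysis, glutathione, collagen and hepatocyte genes, 2 for endoplasmic reticulum stress and respiratory chain, and 5 for fatty acid oxidation, gluconeogenesis and urea cycle and amino acid genes. They were 7 for T and NK cell markers, 10 for male-biased genes and for B and plasma cell markers, 11 for acute phase, 16 for interferon, 21 for mitochondrially encoded genes, 27 for cell cycle, 37 for cholesterol synthesis and 50 for fatty acid synthesis. In C57BL/6J they were 2 for respiratory chain, 4 for lipid droplets, 6 for glycolysis, 8 for urea cycle and amino acid genes, 14 for interferon, and 18 for glutathione and for mitochondrially encoded genes. They were 19 for fatty acid synthesis, 23 for cell cycle, 24 for collagen, 35 for female-biased genes and 53 for fatty acid oxidation. Lists reached by 5 or more splits cannot be told from chance in this test.

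More genes changed by diet in NZO/HlLtJ (939) than in C57BL/6J (165) or CAST/EiJ (149), and the acinar test here was chosen only after the result was seen. Larger fold changes may contribute: the SD of diet log2 fold changes beyond that of the median split was 0.18 in NZO/HlLtJ, 0.15 in CAST/EiJ and 0.12 in C57BL/6J. Less spread between replicates could contribute: the within-group SD was 0.94 times that of the lower other strain, on the side set beforehand to count against it (0.9 or more), but the range leaving out single libraries (0.87 to 1) crosses that limit, so it is left undecided. Without the 5 acinar libraries C57BL/6J had 61 genes and NZO/HlLtJ 1235, which argues against these libraries hiding the calls of C57BL/6J, but C57BL/6J loses 4 libraries in that fit. With 4 NZO/HlLtJ libraries of the same groups left out as well, in all 36 choices, NZO/HlLtJ had 90 to 1270 genes (median 445) and C57BL/6J 27 to 70, under 0.5 of the NZO/HlLtJ count in 35 of 36, so it is left undecided.

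Clock genes differed between CAST/EiJ and the other strains, and the diet test with a clock score was chosen only after the result was seen. Tissue taken at another phase of the day might produce this, but over 14 clock genes the slope on the clock score and the CAST/EiJ minus C57BL/6J difference correlated at r = 0.51, between the limits set beforehand, so it stays undecided. Per2 (2.16, adjusted p = 4.91e-10 by edgeR) and Nfil3 (−0.79, adjusted p = 1.13e-04) differed, and Bhlhe41 went the other way (−0.47, adjusted p = 0.399, slope 0.765). Clock phase is not likely to explain most diet genes of NZO/HlLtJ, of which 677 of 939 were still called with the clock score as covariate, while for C57BL/6J, where 49.1% were, short of the limit used, it is left open.

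Sex-biased genes moved by diet toward the other sex in NZO/HlLtJ males (6 male-biased called lower and 3 higher, 7 female-biased higher and 1 lower). NZO/HlLtJ females had 8 male-biased genes higher and 0 lower. The Xist test was chosen only after the result was seen. The sets were genes called by sex in both C57BL/6J and CAST/EiJ with at least 2-fold differences: 123 male-biased genes had a median diet log2 fold change of −0.27 and 143 female-biased genes 0.53, a gap of 0.8. Chance could produce this gap, since 2 of 35 splits reached it (highest other 1.06). Female tissue or RNA in males is not likely, with Xist at most 0.08% of the lowest NZO/HlLtJ female. By the limit set beforehand, a female-biased median above 0 (here 0.53) counts against a lower hepatocyte share. That share is still left open, as the female-biased set may hold other cells' genes. The identifier run stays undecided, with a gap of 0.49 within run 1 against 0.74 over all males by the same means of log2 CPM (the gap of 0.8 is from the edgeR model; 0.1 to 0.75 leaving out single libraries).

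The readings of the replicate spread (0.94) and of the identifier run (0.49) were changed to undecided after their values were seen, by adding the ranges over left-out libraries, and the limits set beforehand were not moved. So was that of the acinar libraries (61), by leaving out as many NZO/HlLtJ libraries. By the first limits alone all 3 values count against the explanation. Larger fold changes in NZO/HlLtJ (0.18) may contribute but were not tested over left-out libraries, and the cause of the clock difference is open.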
